A study of Mus musculus with 12 samples.

How the data were processed

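Total RNA of mouse peritoneal macrophages, the phagocytes of the abdominal cavity, was extracted with spin columns and measured on the NanoString nCounter, which counts barcoded probes hybridized to each transcript without amplification. The 12 samples form 4 groups of 3: aged mice (20 to 22 months) and young mice (3 to 4 months), each untreated or given PF-044, an antagonist of the prostaglandin E2 receptor EP2, at 2.5 mg/kg per day for 6 weeks by mouth. The series states 3 mice per group, so the replicates are separate mice and the spread between them is biological as well as technical. Whether the untreated mice received a vehicle is not given in the sources used here.

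The deposited values are normalized expression values on the log2 scale, and they were used as they are. The submitters' processing notes name limma with no version or role. Background subtraction, the scaling between samples, the floor and the merging of probe sets are not given in the sources used here. The table holds 1448 gene symbols, of which 1431 match a current symbol and 14 a synonym in the RefSeq gene table of mouse assembly GRCm38.p6, which was used for names only. Transcripts that the probes target are not given there, so no positions are printed. For 5 genes the table has a value under the current and an older symbol, and both were kept.

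No deposited value lies below 20 on the linear scale (4.32 on the log2 scale), and 258 genes sit at that floor in all 12 samples. These were left out, and 1190 genes were tested. Above the floor, the linear values of each sample are whole multiples of a constant step, as counts multiplied by a factor would be. The steps were found separately for 3 sets of genes (658, 367 and 165 genes), and 11911 of 11921 values above the floor (99.9%) lie on a multiple within 0.008 linear units. The search recovered 20 of 20 steps in simulated data. Dividing by the step gives count equivalents, which are inferred from the values. Their sum per sample, over genes above the floor, ran from 533930 to 927614 in 11 samples and was 175127 in aged untreated replicate 2. Raw counts, control probes and the number of lanes were not analysed here, so the counting error of single values is known only through these steps.

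Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend=TRUE) with a coefficient per group, all 12 samples sharing a residual variance per gene with 8 residual and 3.27 prior degrees of freedom. This assumes equal spread in all groups. It fails for genes at the floor in aged untreated replicate 2 but not in the other mice of its group. For these genes the SE and p are too small for age in untreated mice and PF-044 in aged mice. They are too large in the contrasts without aged untreated mice. The 5 contrasts were the age effect in untreated mice, the PF-044 effect in aged mice, that in young mice, the difference between these PF-044 effects, and aged PF-044 mice against young untreated mice. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over the 1190 genes of a contrast, and a gene passed at 0.05. Changes are given in log2 units with the standard error (SE) of the fit, and group levels as mean ± SD of 3 mice.

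Gene lists were fixed before the data were examined, as were the tests, the main alternatives and the rule for named genes. Of 34 lists, 30 had at least 5 tested members. They were compared with all other genes by camera (limma, preset inter-gene correlation 0.01), adjusted over the 30 lists of a contrast. With an estimated correlation, 0 lists passed in any contrast. Camera then gave an unadjusted p under 0.05 for 3, 1, 0, 1 and 3 lists in the order of contrasts above, and fry, which asks only whether the members of a list move on balance one way, passed 25, 17, 1, 17 and 13 lists. Where a camera test is printed for a list that passed, the p with an estimated correlation is given too.

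Named genes are, per contrast, the 10 largest rises and 10 largest falls among the genes that passed, up to 4 members with the smallest p of each list that passed or is described, and a fixed set around EP2 and macrophage activation. Some genes that this rule names are not reported here, while the totals of compared results include them. Il1rn, one of the fixed set, was at the floor in all samples and was not tested.

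The age and PF-044 effects in aged mice share the aged untreated samples with opposite sign, which gives a negative correlation with no effect at all. Their correlation across genes was therefore set against 1000 simulations that keep the shared samples and each gene's residual variance. Other splits of the samples (10 for 3 against 3, 100 drawn for the difference of effects) were counted with the same tests. In data simulated with known changes, between 77.6% and 95.5% of genes changed by 1 log2 unit were recovered, depending on the contrast, and from 3.41% to 6.56% of the calls were false. In 20 simulated runs with no change, some list was called in 1 run, and the T cell list raised by 0.5 was called in all 20. The noise of each gene was drawn independently in these runs, so they do not give the rate of false calls for lists whose members move together.

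Alternatives to the fit were a block for the replicate number, no mean-variance trend, robust variances, sample weights, the groups of a contrast alone, and each of the 12 samples left out in turn. Alternatives to the values were quantile normalization, centring each sample on the median of all genes or on the 4 measured reference genes, and leaving out the 25% of tested genes with the lowest mean. A set of 4 more alternatives was chosen after seeing the data: a common floor of 100, only the 706 genes above the floor in all samples, and centring on the median of these genes over each sample or over each probe set. Common floors from 150 to 800 were added for the share of genes that rose with age only. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used to read the values and draw the figures.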

Results

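Transcripts of 1448 immune-related and other genes were counted in peritoneal macrophage RNA of 12 mice: aged and young, each untreated or given the EP2 antagonist PF-044, with 3 mice in each of the 4 groups. EP2, encoded by Ptger2, is a receptor for prostaglandin E2 that raises cyclic AMP. The normalized log2 value of a sample's median gene lay between 6.11 and 6.58 in 11 samples and at the floor of 4.32 in aged untreated replicate 2. That sample held 741 genes at the floor. Aged untreated replicates 1 and 3 held 333 and 527, and the 9 samples of the other groups held 404 to 467. The lowest value it holds above the floor is 75.9 on the linear scale, against 20.0 to 26.3 elsewhere. A weaker gene is set to 20 in it, which can enlarge falls with age and rises with PF-044 in aged mice. Opposite changes can be reduced likewise. Changes of more than 2-fold with age were 180 falls and 70 rises with this sample, and 141 and 82 without it. In the inferred count equivalents the total of aged untreated replicate 2 was 175127, and those of the other 11 samples ran from 533930 to 927614. The replicates are separate mice, and none was merged. Counts below are therefore also given without aged untreated replicate 2, a choice made after seeing the data. Centring samples on the median of all genes, an alternative scaling, uses the floor as the median of that sample. It shifts all genes alike, by 0.89 log2 units for age, -0.75 for PF-044 in aged mice and -0.69 for the difference between PF-044 effects, against 0.25, -0.12 and -0.06 with that sample left out, so a value that turns sign under this centring alone does so mostly through that sample. With 3 mice per group, the precision of every value is limited.

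**Figure D1:**
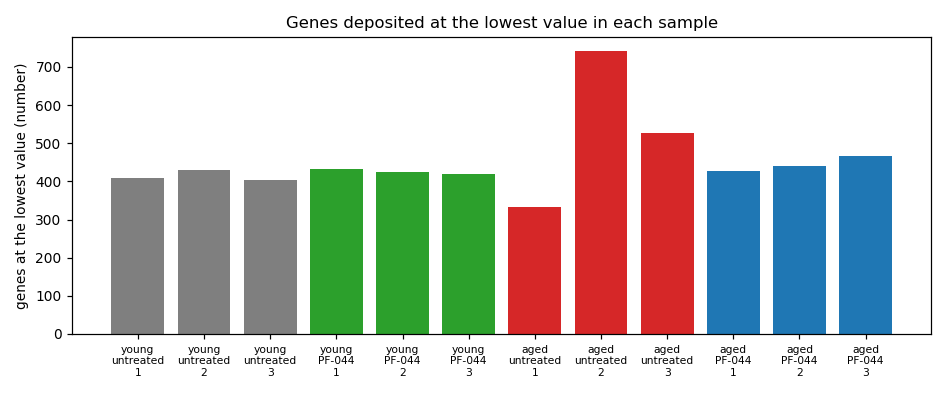
Number of the 1448 genes deposited at the lowest value (vertical axis) in each of the 12 samples (bars, coloured by group). Aged untreated replicate 2 holds 741 such genes, and the 9 samples outside the aged untreated group hold 404 to 467.

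The first comparison asks how cells of aged and young mice differ without the drug. Most B cell and MHC class II transcripts were higher in aged untreated mice, and most markers of T cells, mast cells and resident macrophages and most immediate-early genes were lower. Ms4a1, which encodes the B cell surface protein CD20, stood at 15.21 ± 0.11 (SD, n = 3) in aged and 12.41 ± 0.17 in young untreated mice, a rise of 2.81 log2 units (SE 0.17, limma adjusted p 7.4e-08). The anti-inflammatory cytokine Il10 rose by 2.67 (SE 0.13), from 5.38 ± 0.07 to 8.05 ± 0.09. The scavenger receptor Marco rose by 2.71 (SE 0.11) and the chemokine Ccl22 by 2.63 (SE 0.16). Fn1, which encodes the matrix protein fibronectin, fell by 3.00 (SE 0.09, limma adjusted p 1.1e-09), from 14.02 ± 0.04 to 11.03 ± 0.20. Pf4, encoding platelet factor 4, fell by 2.95 (SE 0.10), and the cyclin D1 gene Ccnd1 by 3.06 (SE 0.11).

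In this comparison 643 of 1190 genes passed, 252 higher and 391 lower in aged mice, and 692 had an unadjusted p under 0.05. Changes of more than 2-fold were 70 rises and 180 falls, or 82 and 141 without aged untreated replicate 2, 54 and 93 with a common floor of 100, and 69 and 88 among the 706 genes above the floor in all samples. In 671 genes (56.4%) the groups did not overlap, where chance gives 10%, and in all 20 genes with the largest changes they did not. Without aged untreated replicate 2, 660 genes passed (280 higher, 380 lower, of which 610 were called with all samples). With a common floor of 100, 560 of 787 genes passed (251 higher, 309 lower). Other large rises were Serinc5 (2.81), F11r (2.56), the Fc receptor gene Fcgr4 (2.50), Ifi27l2a (2.39), Ifit1bl1 (2.32) and Ly6c1 (2.16). Osm (-2.92), Adam8 (-2.86), Fosb (-2.84) and the histamine-forming enzyme gene Hdc (-2.69) fell, and all 4 of these genes are at the floor in aged untreated replicate 2. Thbs1 fell by 2.72. Fcrls was at the floor in all 3 aged untreated mice, and it was at least 3.04-fold lower there.

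Of the 9 MHC class II genes tested, which encode proteins that present antigen to helper T cells, 8 rose and 0 fell over all genes, and 8 rose and 0 fell when adjusted over the list alone (median change 0.83, camera adjusted p 8.3e-05, adjusted p 0.27 with an estimated correlation). H2-Ab1 rose by 1.32 (SE 0.05), H2-DMb2 by 1.15, H2-Aa by 1.48 and H2-Ob by 0.87. The B cell list had 4 rises and 0 falls among 6 genes, also when adjusted over the list alone (median 0.51, camera adjusted p 0.013, adjusted p 0.27 with an estimated correlation). Besides Ms4a1, Blk rose by 1.01 and Cxcr5, which the chemokine receptor list also holds, by 0.20. Cells other than macrophages are present in peritoneal washes, and no sorting step is named in the sources used here.

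Of 15 immediate-early genes that respond to cyclic AMP, 0 rose and 14 fell, with the same counts adjusted over the list alone (median -1.43, camera adjusted p 8.3e-05, adjusted p 0.27 with an estimated correlation). Nr4a1 fell by 1.85 (SE 0.09), Dusp1 by 1.43 and Ier3 by 1.86. Of 18 T cell markers 1 rose and 15 fell, or 2 and 15 adjusted over the list alone (median -1.36, camera adjusted p 0.0062, adjusted p 0.52 with an estimated correlation). Cd28 fell by 1.83 and Cd3e, a chain of the T cell receptor complex, by 1.39, while the inhibitory receptor gene Ctla4 rose by 1.32. Of 9 mast cell and basophil markers 7 fell and 0 rose, also over the list alone (median -1.18, or -1.04 with genes of a group wholly at the floor set to their bound). Camera gave this list an adjusted p of 0.013, and an adjusted p of 0.56 with an estimated correlation. The mast cell protease genes Tpsb2 and Cma1 fell by 2.12 and 1.21, and Il1rl1 by 1.18. Tpsab1 was at the floor in all 3 aged untreated mice, at least 2.05-fold lower.

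Resident peritoneal macrophage markers fell in 6 of 8 genes and rose in 1, also over the list alone (median -1.57, camera adjusted p 0.023, adjusted p 0.43 with an estimated correlation). Another list holds 6 of the 8. Alox15, a lipoxygenase gene of resident peritoneal macrophages, fell by 2.22 (SE 0.09), the adhesion gene Selp by 1.95 and Tgfb2 by 1.19. Gata6, the transcription factor of these cells, fell by 1.96 (SE 0.43, limma adjusted p 0.0021) with replicate 2 at the floor, and gave -1.28 without it. Its aged untreated values (6.61, 4.32 and 6.09) spread far more than the young untreated ones (7.60 to 7.65), so this SE is too small. Timd4 gave -0.04 (adjusted p 0.76). Glycolysis and pentose phosphate genes fell in 11 of 19 and rose in 2, or 13 and 2 adjusted over the list alone, with a median of -0.77 that turns to 0.12 when samples are centred on the median of all genes. Camera gave an adjusted p of 0.023, and an adjusted p of 0.43 with an estimated correlation. Eno1 fell by 1.52 (SE 0.06), Slc16a3 by 1.61, Pfkl by 1.52 and Taldo1 by 0.78, and Taldo1 turns to 0.11 under that centring.

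The prostaglandin and leukotriene list did not pass in this comparison (camera adjusted p 0.053, median -0.61, which turns to 0.28 on centring on the median of all genes). Of its 22 genes 11 fell and 2 rose, also over the list alone. Ptgs1, the constitutive cyclooxygenase, fell by 2.30 (SE 0.06, limma adjusted p 2.6e-10), the thromboxane synthase gene Tbxas1 by 1.73 and Alox5 by 2.16. The inducible cyclooxygenase gene Ptgs2 fell by 1.46 (SE 0.29) with replicate 2 at the floor. Ptger2 rose by 0.60 (SE 0.19, limma adjusted p 0.017), from 5.59 ± 0.16 to 6.19 ± 0.23, a call that ends without young untreated replicate 1 (0.53, limma adjusted p 0.067). Ptger4, encoding the EP4 receptor, fell by 0.55, and centring on the median of all genes turns it to 0.34. Pro-inflammatory cytokines had 4 rises, 5 falls and 6 genes that did not pass, also over the list alone. Their median was -0.05 and their mean -0.12, while camera gave the upward direction (adjusted p 0.79). The median is positive under each of the 5 other scalings. Il1b, encoding interleukin-1 beta, rose by 1.40 (SE 0.22) and Il12a by 1.40 (SE 0.21). The Il1b values of all 3 aged untreated mice and the Ptger2 values of replicates 2 and 3 are no whole multiple of their sample's step, unlike nearly all other values, so how they were derived is not known.

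Interferon-stimulated genes had 4 rises, 3 falls and 9 genes that did not pass among 16, also over the list alone (median 0.28, camera adjusted p 0.20). Ifit1, Ifit3 and Ifit2 rose by 2.15, 1.90 and 1.79, and the transcription factor gene Irf7 by 1.30. Of the fixed genes, the costimulator Cd86 rose by 0.81 (SE 0.10), Tnf fell by 1.21 (SE 0.27) with replicate 2 at the floor, Ccl2 by 1.24, Gsk3b by 0.66, Il6 by 0.60, Arg1 by 0.58 and Akt1 by 0.38. Gsk3b, Il6, Arg1 and Akt1 turn positive on centring on the median of all genes, and Akt1 also on the reference genes. Mrc1 at 0.34 (adjusted p 0.068), Ccr2 at 0.17 and Nos2 at -0.09 did not pass with all samples. Mrc1 passed without aged PF-044 replicate 3 (0.34, limma adjusted p 0.0499).

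How the falls and rises with age divide differs between scalings. The median change of all tested genes was -0.07 as deposited, 0.0034 with quantile normalization and 0.34 with samples centred on the reference genes, and the 0.82 on centring on the median of all genes arises mostly from aged untreated replicate 2. The reference genes themselves differed: Gusb gave -1.51 and Gapdh -0.51, both passed, and Hprt 0.30 and Pgk1 0.10 did not. Gapdh turns to 0.37 on centring on the median of all genes. Directions in this section are those of the deposited scaling. The T cell call was lost with a common floor of 100 (camera adjusted p 0.10, median -0.39 and SD of the changes 0.81 over 16 members) and among the 706 genes above the floor in all samples (0.25, median -0.88, SD 1.05, 8 members), against -1.36 (SD 1.07) over 18 members with all genes. The mast cell call was lost likewise (0.078 and 0.11) with an unchanged median of -1.18 over 7 (SD 0.82) and 5 members (SD 0.80), against 9 (SD 0.84), so with fewer members. The glycolysis and resident macrophage calls were lost among the 706 genes (0.077 for both), with medians of -0.51 over 15 of 19 (SD 0.68, against 0.77) and -1.19 over 7 of 8 members (SD 1.28, against 1.22). The set of 706 genes leaves out 131 of the genes called lower and 5 of those called higher, since a fall to the floor removes a gene from it. The B cell list had 4 members left in both cases, too few for camera, and its call was lost on centring on the median of all genes (0.051).

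In aged mice, the second comparison asks what PF-044 changed. Ccl22, Il10, Il1b and several interferon-induced transcripts that were high in aged untreated mice were lower after treatment, and most T cell and resident macrophage markers and immediate-early genes were higher. Ccl22 fell by 2.72 log2 units (SE 0.16, limma adjusted p 3.3e-07), from 7.48 ± 0.07 (SD, n = 3) to 4.76 ± 0.23, beside 4.85 ± 0.11 in young untreated mice. Il10 fell by 2.18 (SE 0.13) to 5.86 ± 0.02. Il1b fell by 1.63 (SE 0.22, limma adjusted p 1.2e-04), from 7.12 ± 0.19 to 5.49 ± 0.38. Its 3 aged untreated values, from which this fall is measured, are off their sample's step and of unknown derivation. Fn1 rose by 1.85 (SE 0.09), from 11.03 ± 0.20 to 12.87 ± 0.07, and Pf4 by 1.74 (SE 0.10).

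With PF-044 in aged mice 487 genes passed, 306 higher and 181 lower, and 572 had an unadjusted p under 0.05. The groups did not overlap in 545 genes (45.8%, against 10% by chance), nor in the 20 genes with the largest changes. Without aged untreated replicate 2, 512 passed (292 higher, 220 lower), 446 of them shared, and with a common floor of 100 434 of 787 passed (243 higher, 191 lower). Rises of more than 2-fold numbered 78 with all samples, 45 without that replicate, 24 with the common floor and 27 among the 706 genes above the floor in all samples, and falls 29, 39, 16 and 27. Further large falls were Hspb1 (-2.66), a small heat shock protein gene, Serinc5 (-2.34), Ifi27l2a (-2.19), Ifit1 (-2.09), Ifit3 (-1.93), Fcgr4 (-1.55) and Il12a (-1.55). Among the largest rises, the chemokine gene Ccl24 gained 1.87 and Thbs1 1.79. Insr (1.85), Ccr6 (1.83), Fosb (1.83), the T cell coreceptor gene Cd8a (1.75) and Clec7a (1.72) also rose, and these 5 are at the floor in aged untreated replicate 2, without which Fosb gave 1.201.

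T cell markers rose in 15 of 18 genes and fell in 1, also over the list alone (median 0.89, camera adjusted p 0.0042, adjusted p 0.59 with an estimated correlation). Cd28 rose by 1.14, Cd3e by 1.07 and the kinase gene Lck by 0.82, while Ctla4 fell by 0.77. Resident macrophage markers rose in 7 of 8 genes and fell in 0, also over the list alone (camera adjusted p 0.0058, adjusted p 0.59 with an estimated correlation). Their median of 0.73 turns to -0.03 on centring on the median of all genes and is 0.50 to 0.75 under the 4 other scalings. Alox15 rose by 1.53 (SE 0.09), Selp by 0.98 and Tgfb2 by 0.45, which turns to -0.31 under that centring. Gata6 rose by 1.26 (SE 0.43, limma adjusted p 0.035), or by 0.58 without aged untreated replicate 2, in which it is at the floor. Its call ends on leaving out any 1 of 4 samples, the 3 aged PF-044 mice and young untreated replicate 1 (1.23 to 1.28, limma adjusted p up to 0.079).

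Immediate-early genes rose in 10 of 15 and fell in 0, or 11 and 0 adjusted over the list alone (camera adjusted p 0.0058, adjusted p 0.59 with an estimated correlation), with a median of 0.57 that turns to -0.18 on centring on the median of all genes. Nr4a1 rose by 0.90. Ier3 rose by 0.57 and Fos by 0.54, and these turn to -0.18 and -0.21 under that centring. Small macrophage and monocyte markers rose in 5 of 6 genes and fell in 1, also over the list alone (median 0.79, camera adjusted p 0.044, adjusted p 0.59 with an estimated correlation). Csf1r rose by 0.90, Ccr2 by 0.82 and Irf4 by 0.62, which turns to -0.14 under that centring, while Ly6c1 fell by 1.29. This call ended on leaving out any 1 of 4 samples: aged untreated replicates 1 (camera adjusted p 0.091) and 3 (0.072), young PF-044 replicate 2 (0.052) and young untreated replicate 1 (0.052).

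Interferon-stimulated genes fell in 7 of 16 and rose in 3, or 8 and 3 adjusted over the list alone (median -0.64, camera adjusted p 0.016, adjusted p 0.59 with an estimated correlation). Irf7 fell by 1.52 (SE 0.12), while Irf1 rose by 0.44, which turns to -0.32 on centring on the median of all genes. MHC class II genes fell in 5 of 9 and rose in 0, or 6 and 0 adjusted over the list alone (median -0.27, camera adjusted p 0.024, adjusted p 0.59 with an estimated correlation). H2-Ab1 fell by 0.62 and H2-DMb2 by 0.40. H2-Aa gave -0.28 and Ctss -0.44 with limma adjusted p of 0.035 and 0.042, each lost on leaving out any 1 of 8 samples (up to 0.10 and 0.15), and quantile normalization turns H2-Aa to 0.08. The MHC class II call ended without aged untreated replicate 3 (camera adjusted p 0.072) and under quantile normalization (0.24). B cell markers had 1 rise, 2 falls and 3 genes that did not pass (median -0.09, camera adjusted p 0.32). The falls, named after their values were seen, were Ms4a1 (-1.04) and Blk (-0.71). Whether PF-044 changed the mix of cells in these samples or transcripts within a cell type was not tested, in aged or young mice or for the difference between them.

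The prostaglandin and leukotriene list did not pass (camera adjusted p 0.16), with 8 rises and 1 fall among 22 genes, also over the list alone, and a median of 0.23 that turns negative on centring on the median of all genes (-0.53) or on the reference genes (-0.0050). Ptgs1 rose by 1.18 (SE 0.06), Alox5 by 1.10 and Tbxas1 by 0.68, which turns to -0.07 on centring on the median of all genes. Ptger2 at -0.32 (adjusted p 0.21), Ptger4 at 0.11 and Ptgs2 at 0.01 did not pass, and Ptgs2, at the floor in aged untreated replicate 2, gave -0.38 without it. Glycolysis genes rose in 9 of 19 and fell in 1, or 10 and 1 adjusted over the list alone, without passing as a list (camera adjusted p 0.10), and their median of 0.28 turns to -0.48 under the same centring. Eno1 rose by 1.05 (SE 0.06), Slc16a3 by 0.75, Pkm by 0.50 and Taldo1 by 0.39, the last 3 of which turn negative under it (-0.0083, -0.25 and -0.36). Alternatively activated macrophage genes rose in 10 of 18 and fell in 3, or 12 and 3 adjusted over the list alone (camera adjusted p 0.18), with a median of 0.37 that turns to -0.38 under it. The mannose receptor gene Mrc1 rose by 0.68 (SE 0.14) and Arg1 by 0.62 (SE 0.11), and these turn to -0.07 and -0.14.

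Of the other fixed genes Gsk3b rose by 0.26 (turning to -0.50 on centring on the median of all genes) and Cd86 fell by 0.42. Ccl2 rose by 0.54 (limma adjusted p 0.016), a call that ends without aged PF-044 replicate 2 (0.41, limma adjusted p 0.065) and without aged untreated replicate 3 (0.40, limma adjusted p 0.060), and its groups overlap. Tnf gave 0.74 with a limma adjusted p of 0.045, which ends on leaving out any 1 of 10 samples (0.37 to 0.82, adjusted p up to 0.13), the lowest value being that without aged untreated replicate 2. Il6 at 0.04, Akt1 at -0.04 and Timd4 at 0.02 did not pass, and Nos2 was at the floor in both groups. Centring on the reference genes moves the median change of all genes from 0.02 to -0.21, and centring on the median of all genes moves it to -0.73. Under the latter 153 genes passed, 10 higher and 143 lower. Gapdh, 1 of the 4 reference genes, gave 0.38 for PF-044 in aged mice. Its values in all 3 aged PF-044 mice are off their sample's step and of unknown derivation, and they enter centring on the reference genes in each comparison with these mice. With a common floor of 100, 1 list passed, that of resident macrophages (camera adjusted p 0.038), and the T cell list did not (0.12, median 0.25 and SD 0.48 over 16 members, against 0.89 and 0.68 over 18).

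**Figure D2:**
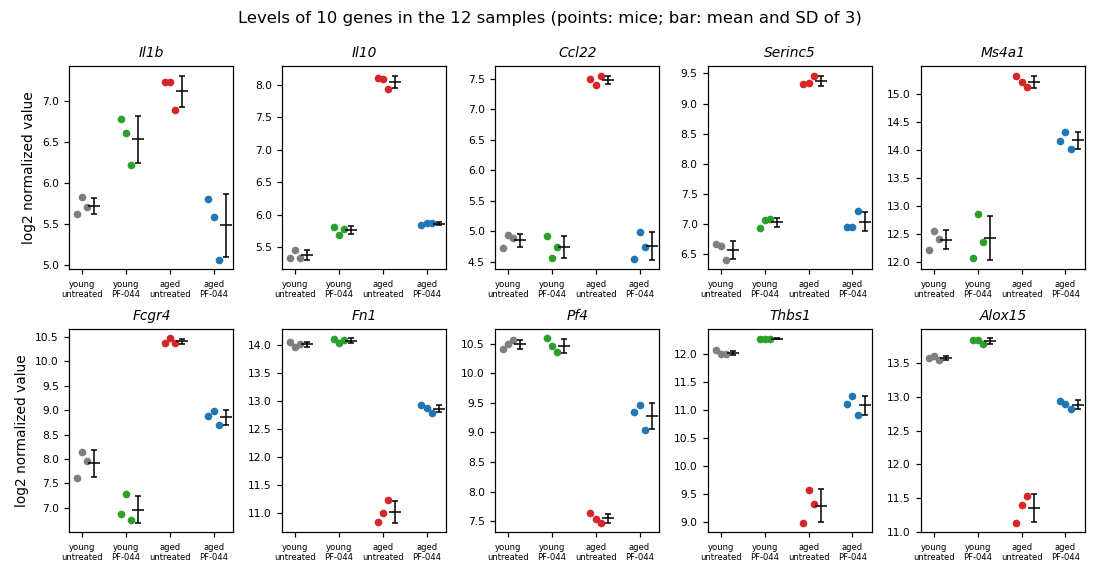
Normalized log2 value (vertical axis) of 10 genes in the 12 mice, 3 per group (points), with the mean and SD of each group (bars). Il10 stands at 8.05 ± 0.09 in aged untreated mice and between 5.38 and 5.86 in the other groups, and Fn1 at 11.03 ± 0.20 in aged untreated mice and between 12.87 and 14.08 in the others.

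The third comparison asks what PF-044 changed in young mice. Changes were smaller: the chemokine receptor gene Ccr2 rose, and 4 of 15 complement genes, 5 of 21 Fc receptor and scavenger genes and 4 of 8 resident macrophage markers fell. Ccr2, a receptor of monocytes, rose by 1.04 log2 units (SE 0.14, limma adjusted p 8.4e-04), from 9.61 ± 0.05 (SD, n = 3) to 10.65 ± 0.15. Cfb, encoding complement factor B, fell by 1.19 (SE 0.09, limma adjusted p 7.5e-06), from 8.201 ± 0.05 to 7.01 ± 0.14. Hspb1 fell by 1.39 (SE 0.17), the chemokine receptor genes Cxcr4 and Ccr7 by 1.16 and 1.02, and Fcgr4 by 0.94.

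In young mice 168 genes passed, 100 higher and 68 lower, and 313 had an unadjusted p under 0.05. Only 1 gene rose and 4 fell by more than 2-fold. The groups did not overlap in 469 genes (39.4%, against 10% by chance). The count was 101 without young PF-044 replicate 1, 111 without young untreated replicate 3, 237 without aged untreated replicate 2 (146 higher, 91 lower), and 226 of 787 with a common floor of 100 (139 higher, 87 lower). It was 388 with sample weights, 280 with the young groups alone, and 0 in limma with samples centred on the median of all genes, where 27 had an unadjusted p under 0.05. Egr2 rose by 0.98, Lif by 0.93, Plau by 0.85, Cd180 by 0.82 and Gata2 by 0.79. Mmp19 fell by 0.99, the glutamine synthetase gene Glul by 0.91 and Arg1 by 0.80. Mmp9 (0.99), Tk1 (0.81) and Fas (-0.86) passed with limma adjusted p of 0.021, 0.016 and 0.019, calls that end on leaving out any 1 of 4, 3 and 4 samples.

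Fc receptor, scavenger receptor and phagocytosis genes fell in 5 of 21 and rose in 0, or 7 and 0 adjusted over the list alone (median -0.19, camera adjusted p 0.0025, adjusted p 0.95 with an estimated correlation). Itgam fell by 0.55 and the phosphatidylserine receptor gene Timd4 by 0.68. Trem1 fell by 0.76, with 2 of 3 treated mice at the floor. Complement genes fell in 4 of 15 and rose in 2, also over the list alone (median -0.24, camera adjusted p 0.016, adjusted p 0.95 with an estimated correlation). C3 fell by 0.66, C1qc by 0.46 and C4a by 0.31. Resident macrophage markers fell in 4 of 8 and rose in 0, or 4 and 1 adjusted over the list alone (median -0.32, camera adjusted p 0.046, adjusted p 0.95 with an estimated correlation). Adgre1, which encodes the macrophage antigen F4/80, fell by 0.66 and Tgfb2 by 0.52, and Cxcl13 gave -0.64 (limma adjusted p 0.016), lost on leaving out any 1 of 4 samples. The resident call ended on leaving out any 1 of 5 samples: aged untreated replicates 1 (camera adjusted p 0.12), 2 (0.062) and 3 (0.056), young PF-044 replicate 2 (0.067) and young untreated replicate 1 (0.074). The complement call ended under quantile normalization (camera adjusted p 0.057).

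Prostaglandin and leukotriene genes had 2 rises, 3 falls and 17 genes that did not pass, also over the list alone (median 0.05, -0.01 on centring on the median of all genes, camera adjusted p 0.97). Alox5ap fell by 0.42 (SE 0.08). Ptgs2 at 0.95 (limma adjusted p 0.048), Ptger4 at 0.55 (0.020), Tbxas1 at -0.26 (0.014) and Ptgs1 at -0.21 (0.036) passed, and these calls end on leaving out any 1 of 9, 4, 4 and 6 samples. Ptger2 gave -0.19 (adjusted p 0.62). Of 15 pro-inflammatory cytokines 2 rose and 0 fell, also over the list alone (median 0.17, camera adjusted p 0.43). Il1b gave 0.82 (SE 0.22, limma adjusted p 0.030), from 5.72 ± 0.10 to 6.54 ± 0.29, a call that ends on leaving out any 1 of 5 samples (0.69 to 0.87, adjusted p up to 0.14): young PF-044 replicates 1 and 2 and each young untreated replicate. Lta (0.67, adjusted p 0.15) and Tnf (0.41, adjusted p 0.40) did not pass with all samples, and passed without aged untreated replicate 2 (limma adjusted p 0.023 and 0.039). Mrc1 at 0.53 (limma adjusted p 0.031) is lost on leaving out any 1 of 6 samples and Akt1 at 0.25 (0.011) without young untreated replicate 3 (limma adjusted p 0.051). Il10 at 0.38 (adjusted p 0.087) passed without aged untreated replicate 1 (limma adjusted p 0.046) or 2 (0.025). Ccl2 (0.41), Il6 (0.17), Gsk3b (0.08), Cd86 (-0.05), Nos2 (-0.09) and Gata6 (-0.12) did not pass.

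The fourth comparison asks whether PF-044 acted differently in aged and young mice, as the difference between its effects. Il1b moved in opposite directions, -1.63 in aged and 0.82 in young mice, a difference of -2.45 log2 units (SE 0.31, limma adjusted p 1.9e-04). Its call in young mice ends on leaving out any 1 of 5 samples (adjusted p up to 0.14), and its 3 aged untreated values are of unknown derivation. Serinc5, Ccl22 and Il10 differed by -2.80 (SE 0.16), -2.62 (SE 0.23) and -2.57 (SE 0.19), falling in aged mice. Fn1 and Pf4 differed by 1.79 (SE 0.13) and 1.76 (SE 0.14), and the chemokine receptor gene Ccr7 by 1.88 (SE 0.10), which rose in aged and fell in young mice. In all 306 genes passed, 178 with a higher and 128 with a lower effect in aged mice, and 433 had an unadjusted p under 0.05. Without aged untreated replicate 2, 363 passed (193 and 170), 291 of them shared, and with a common floor of 100 352 of 787 passed (177 and 175). Centring on the median of all genes left 15 genes (1 and 14), and it moves the median difference of all genes from 0.0029 to -0.69. Centring on the reference genes moves it to -0.23.

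Resident macrophage markers had a higher PF-044 effect in aged mice in 7 of 8 genes and a lower effect in 0, or 8 and 0 adjusted over the list alone (median 1.10, camera adjusted p 1.7e-05, adjusted p 0.12 with an estimated correlation). Thbs1 differed by 1.54, Alox15 by 1.28, Selp by 1.09 and Tgfb2 by 0.97. T cell markers had a higher effect in 12 of 18 genes and a lower effect in 1, or 13 and 1 adjusted over the list alone (median 1.02, camera adjusted p 4.4e-04, adjusted p 0.57 with an estimated correlation). With a common floor of 100 their median was 0.45 over 16 members (SD 0.61, camera adjusted p 0.030), against 1.02 (SD 0.84) with all genes. Cd28 differed by 1.25, Cd3e by 1.18 and Ctla4 by -0.75. Complement genes had a higher effect in 7 of 15 and a lower effect in 0, or 9 and 0 adjusted over the list alone (camera adjusted p 0.013, adjusted p 0.57 with an estimated correlation), with a median of 0.43 that turns to -0.26 on centring on the median of all genes. C1qb differed by 0.82, C1qc by 0.71 and C1qa by 0.58, the last of which turns to -0.11 under that centring.

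Immediate-early genes differed upward in 6 of 15 and downward in 1, also over the list alone (camera adjusted p 0.014, adjusted p 0.57 with an estimated correlation), with a median of 0.47 that turns to -0.23 on the same centring. Their call ended with a common floor of 100 (camera adjusted p 0.10, median 0.37 over 12 members) and held among genes above the floor in all samples (0.029). Dusp1 differed by 0.76. Egr2 gave -0.92, but it is at the floor in 5 of 6 aged mice, so no effect in aged mice was measurable and this value reflects its rise in young mice. MHC class II genes had a lower effect in aged mice in 5 of 9 and a higher effect in 0, or 7 and 0 adjusted over the list alone (median -0.32, camera adjusted p 0.0042, adjusted p 0.57 with an estimated correlation). H2-Ab1 differed by -0.81 and H2-Eb1 by -0.68, while Cd74 (-0.54, limma adjusted p 0.023) and H2-DMb2 (-0.32, 0.024) lose their calls on leaving out any 1 of 6 and 5 samples. Quantile normalization turns Cd74 to 0.01. Interferon-stimulated genes had a lower effect in 6 of 16 and a higher effect in 2, also over the list alone (median -0.57, camera adjusted p 0.0499, adjusted p 0.57 with an estimated correlation). Ifit1 and Ifit3 differed by -1.99 and -1.94, Oas2 by -1.04 and Irf1 by 0.64, which turns to -0.05 on centring on the median of all genes. This call ended without aged PF-044 replicate 2 (camera adjusted p 0.064), young PF-044 replicate 1 (0.071), young untreated replicate 2 (0.067) or young untreated replicate 3 (0.064). It also ended with a common floor of 100 (camera adjusted p 0.18) and among genes above the floor in all samples (0.15).

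For the prostaglandin and leukotriene list the difference did not pass (camera adjusted p 0.15), with 6 genes higher and 0 lower, or 6 and 1 adjusted over the list alone, and a median of 0.04 that turns negative under 3 of the 5 other scalings. Ptgs1 differed by 1.39 (SE 0.08), Alox5 by 1.04 and Tbxas1 by 0.94. Ptger2 (-0.13, adjusted p 0.75) did not pass, nor did Il6, Tnf, Nos2, Mrc1, Ccl2, Gsk3b and Ccr2. Ptger4 (-0.45, adjusted p 0.12) passed without young untreated replicate 2 (-0.59, limma adjusted p 0.031), and Ptgs2 (-0.93, adjusted p 0.11) passed without aged untreated replicate 2 (-1.33, limma adjusted p 5.9e-04). Cd86 (-0.36, adjusted p 0.070) passed without aged untreated replicate 2 or 3 (-0.42 for both), and Gata6 (1.37, adjusted p 0.12) without aged untreated replicate 1 (1.84) or 2 (0.70). Arg1 differed by 1.42, Akt1 by -0.29 and Timd4 by 0.69, which ends near 0 on centring on the median of all genes.

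**Figure D3:**
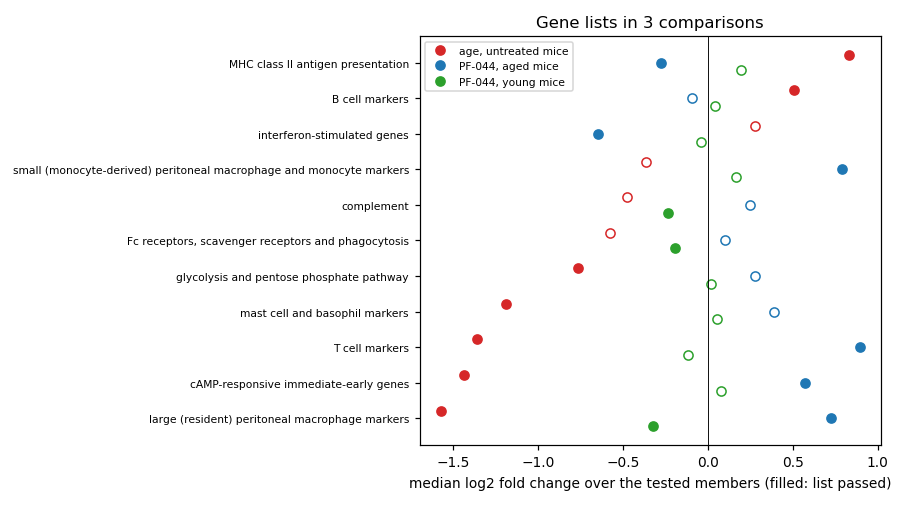
Median log2 fold change of the tested members (horizontal axis) of 11 gene lists (rows) for age in untreated mice, PF-044 in aged mice and PF-044 in young mice, filled where camera passed the list. Resident macrophage markers lie at -1.57, 0.73 and -0.32, and MHC class II genes at 0.83, -0.27 and 0.19. Centring on the median of all genes turns the value of 0.73 to -0.03.

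Treated aged mice were compared with young untreated mice to ask which differences of age were present with the drug. Most B cell and MHC class II genes were higher in treated aged mice, and most immediate-early and mast cell genes and 11 of 22 prostaglandin pathway genes were lower. Marco was higher by 1.79 log2 units (SE 0.11, limma adjusted p 4.0e-07), at 9.33 ± 0.17 (SD, n = 3) against 7.54 ± 0.08. Ms4a1 was higher by 1.76 (SE 0.17). Ccnd1 was lower, at -2.39 (SE 0.11, limma adjusted p 6.0e-08), with 7.36 ± 0.17 against 9.75 ± 0.07. The neutrophil-attracting chemokine gene Cxcl2 gave -1.67 (SE 0.08) and Ccl3 -1.64 (SE 0.13).

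Here 410 genes passed, 178 higher and 232 lower in treated aged mice, 502 had an unadjusted p under 0.05, and 617 (51.8%) had groups that did not overlap, against 10% by chance. Without aged untreated replicate 2, which enters only through the shared variance, 488 passed (210 and 278), 409 of them shared, and with a common floor of 100 413 of 787 passed (184 and 229). Centring on the median of all genes left 22, and sample weights gave 643. F11r (1.52), Prr5 (1.48), Fzd6 (1.45), the B cell attracting chemokine gene Cxcl13 (1.41), Cd180 (1.32), Pdcd1lg2 (1.32) and Cd38 (1.28) were also higher. Ccl17 was at the floor in all 3 young untreated mice and at least 2.77-fold higher with the drug in aged mice. Lower genes included Hdc (-1.83), Osm (-1.67), Hspb1 (-1.57), Adam8 (-1.56) and Trat1 (-1.56). Gzma, encoding granzyme A, was at the floor in all 3 treated aged mice and at least 3.42-fold lower.

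MHC class II genes were higher in 8 of 9 and lower in 0, or 9 and 0 adjusted over the list alone (median 0.66, camera adjusted p 1.5e-05, adjusted p 0.24 with an estimated correlation). H2-Aa stood higher by 1.198, H2-DMb2 by 0.75, H2-Ab1 by 0.71 and H2-Ob by 0.67. B cell markers were higher in 5 of 6 and lower in 0, also over the list alone (median 0.53, camera adjusted p 9.1e-04, adjusted p 0.24 with an estimated correlation), with Blk at 0.30, and Fcer2a at 1.22 with 2 of 3 young untreated mice at the floor. Immediate-early genes were lower in 10 of 15 and higher in 0, or 12 and 0 adjusted over the list alone (median -0.93, camera adjusted p 2.2e-05, adjusted p 0.24 with an estimated correlation). Ier3 gave -1.29, Atf3 -1.13, Dusp1 -1.07 and Nr4a1 -0.95. Mast cell markers were lower in 6 of 9 and higher in 0, or 7 and 0 adjusted over the list alone (median -0.83, camera adjusted p 0.012, adjusted p 0.44 with an estimated correlation), with Tpsb2 at -1.35. Kit was also lower, with 2 of 3 treated aged mice at the floor. The mast cell call ended with a common floor of 100 (camera adjusted p 0.069), with a median of -0.82 over 7 members (SD 0.72, against 0.76 over 9).

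Prostaglandin and leukotriene genes were lower in 11 of 22 and higher in 1, also over the list alone (median -0.42, camera adjusted p 0.028, adjusted p 0.43 with an estimated correlation). Ptgs1 gave -1.12 (SE 0.06), Alox5 -1.06, Tbxas1 -1.05 and Alox5ap -0.91, and Ptgs2 -1.45 (SE 0.29). Ptger4 gave -0.44 (limma adjusted p 0.027), a call that ends on leaving out any 1 of 4 samples, each aged PF-044 replicate and young untreated replicate 2 (up to an adjusted p of 0.12, with -0.29 without the last). Glycolysis genes were lower in 10 of 19 and higher in 1, also over the list alone, without passing as a list (median -0.26, camera adjusted p 0.0501), with Pfkl at -1.09, Pgd at -0.98, Hk1 at -0.71 and Eno1 at -0.48. Of the fixed genes, Mrc1 (1.02), Ccr2 (0.98) and Cd86 (0.40) were higher and Ccl2 (-0.70), Il6 (-0.56), Akt1 (-0.42) and Gsk3b (-0.40) lower. Il10 at 0.48 (limma adjusted p 0.015) is lost without aged PF-044 replicate 2 or young untreated replicate 3 (adjusted p 0.051 for both). Gata6 (-0.70, adjusted p 0.26) and Tnf (-0.48, adjusted p 0.21) passed without aged untreated replicate 2 (limma adjusted p 9.7e-04 and 0.0086). Ptger2 (0.28, adjusted p 0.30), Il1b (-0.24), Nos2 (-0.09), Arg1 (0.03) and Timd4 (-0.02) did not pass. Centring on the reference genes moves the median of all genes from 0 to 0.18.

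Set against each other, the age effect and the PF-044 effect in aged mice ran in opposite directions across genes. Of the 643 genes called for age, 584 (90.8%) had a PF-044 effect of opposite sign, where simulations with the fitted age effect and no drug effect gave 54.5% ± 1.94. Il10 and Ccl22, raised by age, fell with the drug by 2.18 and 2.72, and Fn1 and Pf4, lowered by age, rose by 1.85 and 1.74. Of genes that rose with age 149 fell with PF-044, where 38.3 would fall if the calls were independent, and of those that fell with age 259 rose, against 100.5. Genes that moved alike in both numbered 8 rises and 4 falls, against 64.8 and 59.5. Independent calls are not what shared samples give with no drug effect, and in 1000 simulations with the shared samples and the age effect alone each of these 4 overlaps held at most 2 genes. With no drug effect hardly any gene can pass for PF-044, so small overlaps were given in advance and say nothing about direction. Pearson's r across the 1190 genes, which are not independent replicates, was -0.81 (Spearman's rho -0.81), and simulations in which the shared aged untreated samples were the only link gave -0.50 ± 0.04 with no effect and -0.12 ± 0.03 with an age effect alone. The covariance was -0.39, against -0.023 simulated, a difference of -0.37. All these simulations gave every group the same residual variance per gene, drew genes independently and set no floor. The aged untreated mice varied more, with correlations between replicates of 0.969 to 0.986 against at least 0.995 in the other groups. A noisier shared group gives a stronger negative link with no effect, so the simulated values can be too weak and their SDs too narrow. With the 3 aged untreated mice divided so that the comparisons share none, which leaves 1 mouse on one side, r ran from -0.68 to -0.58 and the covariance from -0.37 to -0.33 over the 6 divisions, a calculation added after the results were seen. The division and the simulations address noise of single mice, and a difference common to all 3 aged untreated samples would still give opposite signs. These 3 have the lowest totals of count equivalents (622732, 175127 and 533930, against at least 644844 elsewhere). A difference of depth, scaling or handling in this group was therefore not separated from an opposite effect of PF-044.

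**Figure D4:**
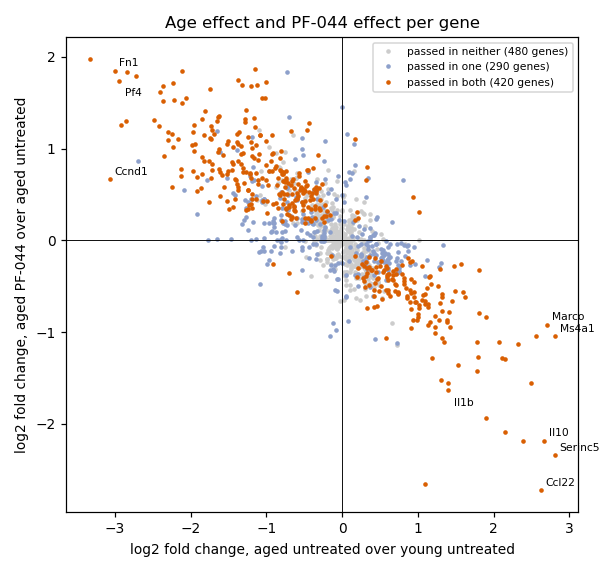
Log2 fold change with age in untreated mice (horizontal axis) against that with PF-044 in aged mice (vertical axis) for 1190 genes (points), coloured by whether a gene passed in neither (480), in 1 (290) or in both comparisons (420). Most of the genes called in both lie in the quadrants of opposite sign, with r at -0.81, and both axes share the 3 aged untreated mice.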

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

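The difference between PF-044 effects, its list tests and the tests of other splits of the samples were planned, and the tests of explanations in the last 3 paragraphs were chosen after the results were seen. The results listed first differ between aged and young mice in their response to PF-044, by a test of the difference itself. It passed 306 genes and 6 lists. Of 100 assignments of the drug within ages, 2 gave as many genes, the real one included. The other of these 2, with 425 genes, exchanges the drug labels in aged mice only and so measures the sum of the PF-044 effects at both ages. Of the rest, 9 assignments that keep the drug groups of the aged mice gave 183 to 261 genes and the other 89 gave 0 to 5, so a large part of the count can arise with the real groups in aged mice alone. The count of 2 in 100 argues against a chance assignment to all mice. It does not test the difference between ages, since shuffling the aged mice also removes the PF-044 effect in them. With the aged groups kept, none of the 9 reached 306 genes, but so few cannot give a share under 0.05. Chance is therefore not excluded for the difference. For lists, 5 of 100 assignments gave at least 6, the highest other 7, so chance is not excluded.

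Large upward differences, with all samples, were Fosb (2.25), Ccr9 (2.03), Emp1 (1.93), Cd27 (1.90), Ccr7 (1.88), Stat4 (1.87), Cd8a (1.83), Fn1 (1.79) and Pf4 (1.76). Aged untreated replicate 2 is at the floor in Fosb, Ccr9, Emp1, Cd27, Stat4 and Cd8a, and without it these gave 1.62, 1.85, 1.65, 1.36, 1.36 and 1.53. Ccr9 is at the floor in aged untreated replicate 3 and young PF-044 replicate 1 as well. The largest downward ones among named genes were Serinc5 (-2.80), Ccl22 (-2.62), Il10 (-2.57), Il1b (-2.45), Ifit1 (-1.99), Ifit3 (-1.94), Ifi27l2a (-1.82), Il12a (-1.57), Ly6c1 (-1.49) and Hspb1 (-1.27).

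The lists that passed were resident macrophages (camera adjusted p 1.7e-05), T cells (4.4e-04), MHC class II (0.0042), complement (0.013), immediate-early genes (0.014) and interferon-stimulated genes (0.0499). With an estimated correlation none of these calls holds, with adjusted p 0.12 for resident macrophages and 0.57 for the other 5. With a common floor of 100 the immediate-early and interferon calls end (camera adjusted p 0.10 and 0.18). Resident macrophage and prostaglandin genes included Thbs1 (1.54), Ptgs1 (1.39), Alox15 (1.28), Selp (1.09), Alox5 (1.04), Tgfb2 (0.97) and Tbxas1 (0.94). T cell genes included Cd28 (1.25), Cd3e (1.18) and Ctla4 (-0.75). MHC class II genes included H2-Ab1 (-0.81), H2-Eb1 (-0.68), Cd74 (-0.54) and H2-DMb2 (-0.32). Complement genes included C1qb (0.82), C1qc (0.71), C1qa (0.58) and Cd55 (0.45). Immediate-early genes included Dusp1 (0.76), Fos (0.47) and Egr2 (-0.92), whose effect in aged mice was not measurable with 5 of 6 samples at the floor, and interferon-stimulated genes Oas2 (-1.04) and Irf1 (0.64). Of the fixed genes, Arg1 (1.42), Timd4 (0.69) and Akt1 (-0.29) passed.

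The 4 comparisons of 3 mice with 3 allow 10 splits each, too few for a share under 0.05, and in each only 1 split, the real one, gave as many genes or lists. The age effect had 643 genes (highest other 0) and 7 lists (6), and PF-044 in aged mice 487 genes (1) and 6 lists (2). PF-044 in young mice had 168 genes (0) and 3 lists (2), and aged PF-044 mice against young untreated mice 410 genes (0) and 5 lists (4).

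With age in untreated mice more genes fell than rose: 39.2% of the genes that passed rose. Without aged untreated replicate 2, the sample of low counts, the share was 42.4%, which stays below 50% by more than the spread over left-out samples (1.72 points) and argues against that sample as the whole cause. With a common floor of 100, above the lowest measured value of every sample, it was 44.8%, which argues likewise against a higher detection limit in the aged untreated group as the whole cause, although it was 51.3% with a common floor of 400, so the excess of falls depends on weakly expressed genes. The scaling of the deposited values may cause it: centred on the reference genes, 71.3% rose, but those genes differ among themselves by 1.80 log2 units. Over the 5 other scalings the share ran from 45.5% to 90.6%, the highest on centring on the median of all genes. Among the 706 genes above the floor in all samples it was 49.6%, a set that leaves out more genes called lower than called higher. Scaling and an effect of age cannot be told apart here.

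B cell markers rose with age while T cell, mast cell and resident macrophage markers fell. A larger share of B cells alone would raise all B cell markers alike, and the changes of Ms4a1 and Cxcr5 differ by 2.61 log2 units (SE 0.18), which argues against it as the whole cause. It would also lower alike the markers of other cells that B cells do not express. Over the 20 members of these 3 lists above the floor in all samples the changes within a list had an SD of 1.09, against a standard error of 0.13. The falls were therefore unequal, so a larger share of B cells is not their only source if B cells express none of these markers. Any further change of single genes gives this result, so it does not tell how much of the falls a larger share of B cells made. The medians of the 3 lists differ by 0.31 (permutation p 0.798), which shows neither that the cell types fell apart nor that they fell alike. A larger share of B cells as part of the cause stays open, and a change in B cells and an effect of age on each cell type were not tested.

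Il1b is off the step of its sample in all 3 aged untreated mice (150.5, 150.6 and 119.3 on the linear scale). Averaging of several probe sets for these genes would move it off the step in every sample, and 9 of its 12 values lie on it, which argues against that. A separate step or repeat measurement for these samples may be the source. With 10 such values in the whole table, too few to find a further step, this cannot be told apart from other handling. No biological explanation was tested.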

How the results depend on the processing

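Of the alternatives below, the common floor of 100, the use of only genes above the floor in all samples, and centring on the median of those genes or of each probe set were chosen after seeing the data. The other alternatives were planned. For 293 results on single genes, 7142 comparisons with alternatives gave 6734 with the same direction and side of the threshold, 322 weaker, 57 newly passing and 29 reversed. For 27 list results, 592 of 690 comparisons kept the call, 98 lost it and 0 reversed. For 10 counts, 221 of 253 stayed within 1.5 times.

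With an estimated inter-gene correlation, camera passed 0 lists in each of the 5 contrasts, and unadjusted p under 0.05 were 3, 1, 0, 1 and 3, while fry passed 25, 17, 1, 17 and 13. The cause was not tested. Sample weights gave 11 lists for age, 388 genes for PF-044 in young mice, and 643 genes and 9 lists for aged PF-044 against young untreated mice. Centring on the median of all genes, which in aged untreated replicate 2 is the floor itself, left 153 genes for PF-044 in aged mice, 0 in young mice (limma, 27 with an unadjusted p under 0.05), 15 for the difference and 22 for aged PF-044 against young untreated mice. Centring on the reference genes gave 107 genes for PF-044 in young mice and 8 lists in the last comparison. The groups of the contrast alone gave 280 genes for PF-044 in young mice. Only genes above the floor in all samples, a smaller set, gave 3 lists for age, 1 for PF-044 in aged mice and 3 in the last comparison. A common floor of 100 gave 1 list for PF-044 in aged mice. Quantile normalization, and centring each probe set, gave 1 list each for PF-044 in young mice, and centring on the genes above the floor in all samples gave 8 lists in the last comparison. Except for the smaller sets of genes and that median at the floor, the cause was not tested.

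The shares of rises moved by over 10 points with scaling. For age, 452 rose and 47 fell centred on the median of all genes, and 552 and 222 centred on the reference genes, 403 and 316 on the median of genes above the floor in all samples, and 375 and 327 by probe set. For PF-044 in aged mice these were 10 and 143, 158 and 295, 241 and 260, and 245 and 288.

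A block for the replicate number gave 651, 502, 166, 319 and 416 genes in the order of contrasts. Under it 4 of 293 results on single genes lost their call and 2 newly passed, and 2 of 27 list calls were lost. The numbers do not pair samples: the 18 pairs of samples with the same number correlated at -0.15 to 0.33 after group means were removed, and 4 of 12 samples correlated best with their own number.

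Leaving out each sample in turn gave 572 to 660 genes and 7 to 10 lists for age, and 389 to 512 and 4 to 7 for PF-044 in aged mice. PF-044 in young mice gave 101 to 237 and 2 to 3 (101 without young PF-044 replicate 1, 111 without young untreated replicate 3). The difference gave 255 to 363 and 5 to 8, and the last comparison 336 to 488 and 5 to 8, with 8 lists without aged untreated replicate 2. The correlation of the age and PF-044 effects ran from -0.83 to -0.80, and was -0.79 with sample weights and -0.83 without the 25% of genes with the lowest mean.

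Reversed on centring on the median of all genes were, for age, Taldo1 (0.11), Ptger4 (0.34), Il6 (0.29), Arg1 (0.30), Akt1 (0.50) and Gsk3b (0.22). For PF-044 in aged mice they were Irf1 (-0.32), Irf4 (-0.14), Tbxas1 (-0.071), Fos (-0.21), Ier3 (-0.18), Taldo1 (-0.36), Pkm (-0.25), Slc16a3 (-0.0083), Tgfb2 (-0.31), Tnf (-0.019), Arg1 (-0.14), Mrc1 (-0.074), Ccl2 (-0.21) and Gsk3b (-0.50). For the difference they were Irf1 (-0.051), Cd55 (-0.24), C1qa (-0.11), Fos (-0.23) and Timd4 (-0.00025). Centring on the reference genes reversed Akt1 (0.025) and Timd4 (0.37) for age, and quantile normalization H2-Aa for PF-044 in aged mice (0.080) and Cd74 for the difference (0.013). Beyond the shift of all genes by each scaling, the cause was not tested.

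A pseudocount and a count model were not run, since the values are normalized and on the log2 scale, and robust variances do not apply to camera. Depth limits the aged untreated group most: in replicate 2 no gene below 75.9 on the linear scale was measured. That limit is of the set of genes with a step of 3.80, and it is higher in the sets with steps of 4.65 and 4.57. The Ptger2 value of replicate 2, 80.0, is 17.5 steps, below the 20 steps of the lowest value on a step in its set.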

Other observations

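The gene and list tests in this part were planned, and the comparison of the PF-044 effects at both ages, the search for values off a step and the comparison of symbols were chosen after the data were seen. Chemokine genes moved both ways with age, with 4 rises, 7 falls and 15 genes that did not pass (median -0.02, camera adjusted p 0.81): Ccl22 rose by 2.63 and Pf4 fell by 2.95. With PF-044 in aged mice 6 rose and 1 fell, the latter Ccl22 (-2.72), with Ccl24 (1.87) and Pf4 (1.74) among the rises. Matrix and angiogenesis genes fell with age in 6 of 14 and rose in 0 (median -0.46, camera adjusted p 0.093), with Fn1 at -3.00 and Thbs1 at -2.72. NK and cytotoxic markers fell with age in 7 of 12 and rose in 0 (median -0.73, camera adjusted p 0.051).

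Fc receptor and scavenger genes moved both ways with age, with 6 rises and 12 falls among 21 (median -0.58, mean -0.13, camera adjusted p 0.75), and Marco and Fcgr4 among the rises. For inflammasome genes the median with age was 0.63 and the mean -0.18, and for alternatively activated macrophage genes -0.26 and 0.11, so no direction is given. Lists of senescence (3 genes tested), eosinophil (4), mesothelial (2) and reference genes (4) were too small for camera. Of the senescence genes 2 fell with age, and of the mesothelial genes 0 passed with limma in any contrast.

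The PF-044 effects in aged and young mice correlated at r 0.26 across 1190 genes (rho 0.27). Of 100 assignments of the drug within ages 2 gave as large a size, the real one included (permutation p 0.02, largest other 0.31). Of genes that passed in both, 45 rose and 28 fell in both, against 25.7 and 10.3 if the calls were independent, and 21 and 19 moved in opposite directions, against 17.5 and 15.2. The aged and young comparisons share no sample, but their tests share the residual variance of each gene. Independent calls are therefore not what unrelated effects would give.

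Besides Il1b, the values off their sample's step are Ptger2 in aged untreated replicates 2 (80.0 on the linear scale) and 3 (60.7) and young PF-044 replicate 2 (36.2), Ptges in aged untreated replicate 2 (80.0), and Gapdh in all 3 aged PF-044 mice. The 5 genes listed under a current and an older symbol have different values under each, with median differences of 1.07 log2 units for Pclaf, 1.45 for Cd244a, 0.63 for Chil3 and 3.51 for Hras, and 0 for Ptgdr2.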
